A study of Nitrosomonas europaea ATCC 19718 with 9 samples.

How the data were processed

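Single-colour arrays of 3 control, 3 exposed and 3 recovered samples of Nitrosomonas europaea were used. Per the labels' protocols, RNA was taken up in Trizol, extracted on silica columns and labelled with Cy3 as amplified complementary RNA. The spot intensities were produced with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers these intensity values are background-subtracted and come with median spot and local background intensities and with flags for outliers, saturation and being well above background. A table of the authors' normalized log2 values was deposited for the same arrays, and 9 further columns of raw values in it were not used. The authors also deposited tables of their own comparisons, with a fold change and a p-value per gene. How the authors normalized and tested the values is not given in the sources used here.

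From the scanner values, log2 of the processed intensity was taken over 14616 non-control spots and the 75th percentile of each array was subtracted. Outlier spots were left out and the 6 spots of each of 2436 probes were averaged. A probe was kept when more than a share of 0.5 of its spots were well above background on all arrays of at least 1 group, which left 2383 genes. Each gene had 1 probe. Gene names, products and coordinates were taken from the authors' table, which annotates 2402 probes. The other 34 had no annotation in it, and 4 of the tested genes are among them. Coordinates are counted from 1 on the chromosome, and no genome sequence was used here. Where a group was not well above background on any of its arrays, a change is given as at least N-fold, taking for each array of the dim group the higher of its lowest signal well above background and the probe's own.

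The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes in 1 fit over all 9 arrays, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit had 6 residual degrees of freedom, a prior of 3.14 degrees of freedom and a prior SD of 0.0961 (log2). The 3 contrasts were exposed minus control, recovered minus exposed and recovered minus control. A total of 20 gene lists were tested with camera at a correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. No list passed with an estimated correlation. Overlaps between contrasts were set beside 100 simulations of unchanged groups, with normal noise of equal size per gene in every group. The design, the lists, the rule for named genes and most alternatives were written before the data were examined.

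The rule for named genes took, per contrast, the 10 largest rises and 10 largest falls among genes past the test whose 3 values in each group did not overlap. It added metal and ammonia oxidation list members past the test with at least a 2-fold change (at most 6 per list), up to 4 members past the test of every other list, and amoA, amoB, amoC, hao, nirK, merA, the Rubisco large subunit and nitrosocyanin. Genes outside this rule are named where the text says so or as further members of a list. The annotation calls the copper nitrite reductase gene aniA.

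The gene test was tried on simulated log2 values for 2383 genes, with independent normal noise of equal size per gene in every group. Background correction, probe filters, scaling and the unequal spreads of the groups were not part of this trial. For exposed against control, 30% of genes changed by 0.25 (log2), 96% of those changed by 0.5 and 100% of those changed by 1 were recovered. Of unchanged genes, 0.412% were called. At 0.5, 90% were recovered for recovered against exposed and 86% for recovered against control. At 1 these shares were 96% and 98%. Spots of 1 probe gave a standard error of 0.0154 to 0.0272 (log2) per array, and the median SD between arrays of a group was 0.046 in control, 0.086 in exposed and 0.12 in recovered cells. Of the 9 arrays, 8 lay on 1 slide and recovered 3 on another. Alternatives covered background correction, scaling, probe filters, the authors' values, blocks for replicate number, slide and slide row, the arrays in the fit, the variance model, the test, a fold threshold and leaving out each array. Because the files hold no mean spot signal, normexp used the median spot signal with an offset of 50.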

Results

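Genome-wide transcript levels were measured in Nitrosomonas europaea, a bacterium that lives by oxidising ammonia to nitrite and fixes its own carbon. The cells were grown in a stirred continuous culture and sampled in 3 states with 3 arrays each. Control cells received no nanoparticles. Exposed cells had been fed 50 ppm zinc oxide nanoparticles until ammonia removal had declined by 10%. Recovered cells were exposed cells that, once the particles had been removed, spent 12 h in fresh medium. The submitters describe 3 independent experiments per state. The labels do not say whether these were separate reactor runs, so the p-values below measure the spread between these samples. Every array was a single-colour hybridisation carrying 6 spots per probe, and 2383 genes passed the detection filter. The 75th percentile of the spot intensity was 629 ± 49.0 in control, 426 ± 7.54 in exposed and 834 ± 285 in recovered arrays (mean ± SD, n = 3). Between 91.0% (exposed 2) and 98.7% (recovered 2) of spots lay well above background, and 0 spots were saturated. All gene values are log2 signal relative to the 75th percentile of the array. The first principal component held 55.6% of the variance and parted control from exposed arrays, with recovered arrays between them, and the second held 30.9% and set the recovered arrays apart. The number of arrays limits the precision of every value.

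The first comparison asks how cells respond to the nanoparticles. Exposed cells carried more transcript of the efflux genes czcC and czcB and of mercury resistance genes, and far less of the nitrite reductase gene cluster. czcC (NE1640), the outer membrane part of a zinc, cobalt and cadmium efflux pump, rose 3.93-fold, from -2.88 ± 0.06 to -0.90 ± 0.05 (log2 signal, mean ± SD, n = 3). Its neighbour czcB (NE1639), the membrane fusion part, rose by 1.18 on the log2 scale. NE0925, a c-type cytochrome encoded beside the nitrite reductase, fell 6.75-fold, from 0.92 ± 0.13 to -1.84 ± 0.09. The largest rise was in NE2571, a protein of the metallo-beta-lactamase superfamily (position 2808678 to 2809541 of the chromosome, plus strand), at 7.90-fold (log2 change 2.98, SE 0.054, adjusted p = 1.7e-09).

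Of the 27 measured members of the heavy metal list, 11 rose, 10 fell and 6 did not pass the test; 21 passed when adjusted over the list alone. The rises were led by czcC and by the mercury resistance genes. merP (NE0841), the periplasmic mercury-binding protein, rose by 1.83 (SE 0.19, adjusted p = 3.25e-05), and merT (NE0842), the mercuric ion transporter, rose by 1.20. merA (NE0839), the mercuric reductase, rose by 1.07 (SE 0.27, adjusted p = 0.00697). merC (NE0840) was not well above background in any control array and was well above it on 2 of the 3 exposed arrays, so its rise is given as at least 2.06-fold. The falls in this list were led by copper proteins of the nitrite reductase cluster, pan1 (NE0927, log2 change -1.76) and aniA (NE0924, log2 change -1.45). The list as a whole did not stand apart from other genes (camera adjusted p = 0.920, and 0.962 with an estimated correlation). It takes in genes with copper in their product name, such as these, so its test does not speak for metal resistance genes alone.

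In the list for nitrogen oxide metabolism, 6 of 15 genes fell, 2 rose and 7 did not pass the test, and 8 passed when adjusted over the list alone. The 4 largest falls lay side by side on the minus strand. They were NE0925 (-2.75, SE 0.16, adjusted p = 7.39e-07), NE0926 (a second c-type cytochrome, -2.65), pan1 (-1.76) and aniA (-1.45), where aniA encodes the copper-containing nitrite reductase that turns nitrite into nitric oxide. The list test gave adjusted p = 0.0624 (adjusted p = 0.370 with an estimated correlation).

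Of 11 measured ammonia oxidation genes, 3 rose, 1 fell and 7 did not pass, and 4 passed when adjusted over the list alone. The list as a whole did not stand apart from other genes (camera adjusted p = 0.920; adjusted p = 0.962 with an estimated correlation), and its members ranged from -0.38 to 0.85. amoC3 (NE1411), a separately encoded subunit of ammonia monooxygenase, rose by 0.85 (SE 0.074, adjusted p = 9.84e-06). amoC1 (NE0945) and amoC2 (NE2064) rose by 0.28 and 0.24, but their changes were -0.31 and -0.45 under quantile normalization and -0.31 and -0.46 in the authors' normalized values. amoA1 (NE0944, -0.27, adjusted p = 0.103), amoB1 (NE0943, -0.38, adjusted p = 0.155) and hao2 (NE0962, hydroxylamine oxidoreductase, -0.20, adjusted p = 0.371) did not pass. The genome holds near-identical copies of these genes, so a probe may read more than 1 copy and the values per copy are uncertain.

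Most carbon fixation genes rose. Of 15 members of this list, 11 rose and 2 fell, with 13 passing when adjusted over the list alone, a median log2 change of 0.52 and a camera adjusted p of 0.0420 (adjusted p = 0.370 with an estimated correlation). cbbP (NE1474), the phosphoribulokinase that regenerates the carbon dioxide acceptor, rose by 0.99 (SE 0.051), and cbbG (NE0327), a glyceraldehyde 3-phosphate dehydrogenase, rose by 1.01. rbcL (NE1921), the large subunit of the carbon-fixing enzyme Rubisco, rose by 0.38, but its change was -0.23 under quantile normalization and -0.20 in the authors' normalized values. Fatty acid synthesis genes also rose, 9 of 11 with 1 falling and 10 passing when adjusted over the list alone (camera adjusted p = 0.0420; adjusted p = 0.370 with an estimated correlation). plsX (NE1645), which starts phospholipid synthesis, rose by 1.71, fabH (NE1646), which starts fatty acid chains, by 1.35, and accC1 (NE0653), a biotin carboxylase, by 1.02. With normexp background correction the fatty acid list gave a camera adjusted p of 0.105, and with median centring 0.0526.

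Respiratory chain genes fell more often than they rose, 14 against 5 of 29, with 19 passing when adjusted over the list alone (camera adjusted p = 0.0463; adjusted p = 0.370 with an estimated correlation). coxA2 (NE0683), the main subunit of a terminal cytochrome oxidase, fell by 0.92, while nqrF (NE2392), part of a sodium-pumping quinone reductase, rose by 1.01. Quantile normalization gave a camera adjusted p of 0.196 for this list, and median centring gave 0.0615. Flagella and chemotaxis genes fell in 17 of 41 cases and rose in 4, with 20 passing when adjusted over the list alone (camera adjusted p = 0.0463; adjusted p = 0.879 with an estimated correlation). With normexp background correction that list pointed the other way (adjusted p = 0.528). Its camera adjusted p was 0.0980 with median centring and 0.0605 with no filter on dim probes. The chemotaxis genes cheZ1 (NE1924) and cheY (NE1923) went against the list, rising by 0.93 and 0.91.

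Other lists held members that moved both ways, and none of them passed camera in this comparison. Counts within a list are to be read beside the share of all genes that passed. That share was 64.6% here, 56.5% for recovered against exposed and 58.5% for recovered against control. Among aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, 13 of 21 rose and 4 fell, and 17 passed when adjusted over the list alone. They were led by serS (NE0180, seryl-tRNA synthetase) with a rise of 1.56, and the list test gave adjusted p = 0.162 (adjusted p = 0.370 with an estimated correlation). In the efflux list 11 of 29 rose and 8 fell, with 19 passing when adjusted over the list alone, and mexE (NE0156), a membrane fusion protein of a multidrug pump, rose by 1.94. Of 56 ribosomal protein genes, 21 rose, such as rpmF (NE1644, 1.64), and 26 fell, such as rplQ (NE0427, -1.17), and 49 passed when adjusted over the list alone. Chaperone and protease genes fell in 9 of 21 cases and rose in 5, with 15 passing when adjusted over the list alone, and clpB (NE2402), a disaggregase, fell by 0.92. Of 23 oxidative stress genes 8 rose and 8 fell, with 16 passing when adjusted over the list alone, and the peroxidase-like gene NE2038 rose by 1.54. The 9 ATP synthase genes divided evenly, 3 rising and 3 falling, with 6 passing when adjusted over the list alone, from atpB (NE0200, 1.14) to atpC (NE0207, -0.69). Of 41 iron uptake genes 8 rose and 11 fell, with 19 passing when adjusted over the list alone. The outer membrane receptor NE0636 rose 2.83-fold and NE1531, another receptor, fell by 1.32.

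The remaining lists were cell envelope synthesis (10 of 21 rose and 2 fell), toxin-antitoxin systems (8 of 15 and 2), DNA repair (8 of 23 and 8), transposases (12 of 37 and 7), cytochrome c maturation (4 of 13 and 4) and ECF sigma factors (2 of 20 and 4). Passing when adjusted over the list alone were 11, 10, 16, 19, 8 and 4 of these genes. NE1176, a peptidoglycan-binding protein, rose by 1.39, mutY (NE0056), an adenine glycosylase, by 0.72, and ccmC (NE0766), a heme exporter, by 0.85. The toxin-antitoxin list also caught the peptide release factors prfA (NE1913, 0.56) and prfB (NE1229, 0.50), which terminate translation.

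Outside the lists, the largest rises after NE2571 were the hypothetical proteins NE1545 (2.90) and NE0512 (2.73), apt (NE0181, adenine salvage, 2.68), a tRNA for isoleucine (2.49), the SCO1/SenC protein NE0509, of a family that delivers copper to cytochrome oxidase (2.46), and gatA (NE2072, 2.44), part of a tRNA-amidating enzyme. Further large falls were the hypothetical proteins NE2151 (-2.33), NE2153 (-2.14) and NE2152 (-1.96), metE (NE1436, methionine synthesis, -1.70) and Rh50 (NE0448, an ammonium transporter, -1.37). In all, 1540 of 2383 genes passed limma's test at adjusted p under 0.05, with 845 higher and 695 lower. The change reached 2-fold in 195 of them, 159 higher and 36 lower. These counts include stable RNA probes, and 36 of 40 tRNAs rose past the test, with a median log2 change of 1.11 over all 40. The balance of higher to lower moved with the processing: 54.9% of called genes were higher here, against 37.3% with median centring and 71.0% with normexp background correction on the median spot signal.

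**Figure D1:**
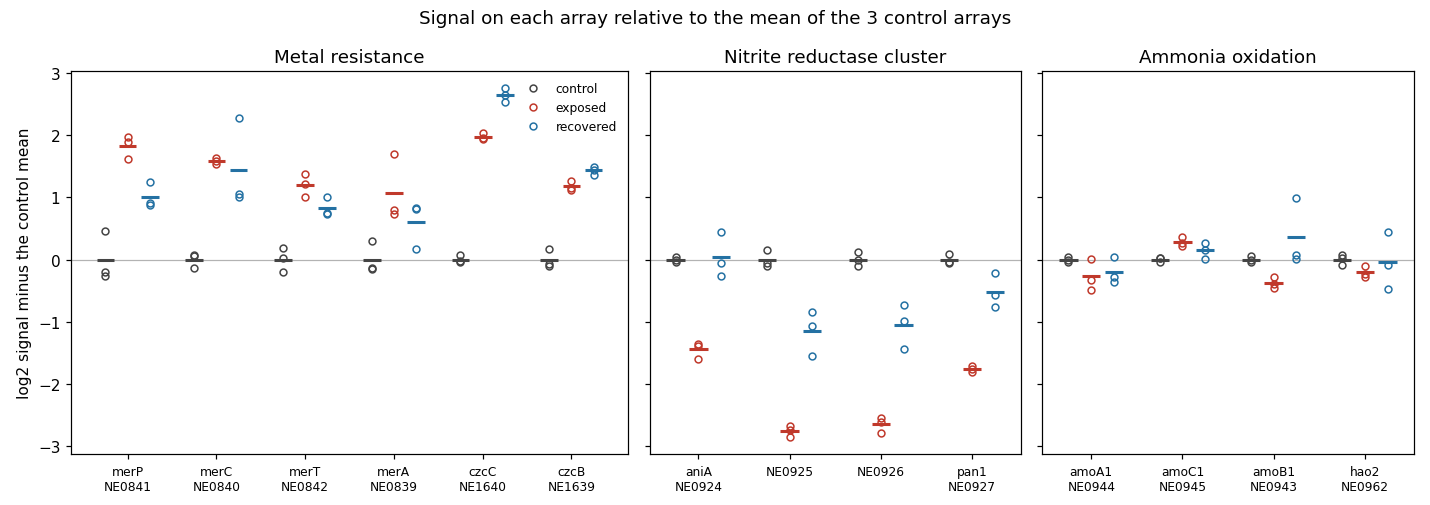
Log2 signal on each array minus the control mean (vertical axis) for metal resistance, nitrite reductase cluster and ammonia oxidation genes (horizontal axis); circles are arrays, 3 per group, and bars are group means. czcC stood 1.98 above control in exposed and 2.65 above it in recovered cells, NE0925 stood at -2.75 and -1.16, and the control values of merC were not well above background.

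The authors' deposited table for this comparison lists 109 genes as higher and 50 as lower. All 50 fell here and 108 of the 109 rose here. The exception was NE0375, a heavy metal efflux pump of the CzcA type (420140 to 423244, plus strand). The authors' deposited table lists it as 2.03-fold higher, while the group means in the same table are 6.59 in exposed and 7.61 in control cells. Its log2 change here was -0.82. NE0375 is discussed because of this difference and was picked for this after its values were seen.

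The second comparison asks what changed during the 12 h without particles. No unexposed culture was sampled after 12 h in fresh medium. Removal of the particles therefore cannot be told apart from the fresh medium, handling and time. The nitrite reductase cluster rose again and NE2571 fell back. NE0925 and NE0926 both rose by 1.60 (SE 0.16 for each, adjusted p = 4.15e-05 and 4.43e-05), aniA by 1.48 and pan1 by 1.24. The largest rise was in metE, at 4.97-fold (log2 change 2.31, SE 0.25, adjusted p = 6.84e-05), from -3.09 ± 0.22 to -0.77 ± 0.60 (mean ± SD, n = 3). NE2571 fell 6.74-fold (log2 change -2.75, SE 0.054, adjusted p = 3.5e-09), and 7 of the 10 largest falls were tRNAs, among them those for aspartate (tRNAAsp1, -2.71) and tryptophan (tRNATrp1, -2.65).

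Nitrogen oxide genes rose in 11 of 15 cases and fell in 1, with 12 passing when adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.520 with an estimated correlation). Respiratory chain genes rose in 17 of 29 cases and fell in 4, with 22 passing when adjusted over the list alone (camera adjusted p = 0.0190; adjusted p = 0.387 with an estimated correlation). coxA2 rose by 1.16 and nuoI (NE1769), a subunit of the proton-pumping NADH dehydrogenase, by 0.98, while nqrC (NE2395), of the sodium-pumping enzyme, fell by 1.08. Among ammonia oxidation genes 5 of 11 rose and 1 fell, with 6 passing when adjusted over the list alone. amoB1 rose by 0.73 (SE 0.22, adjusted p = 0.0173), cyt_c552 (NE0102), an electron carrier, rose by 0.81, and amoC3 fell by 0.37. amoA1 (0.07, adjusted p = 0.666) and hao2 (0.16, adjusted p = 0.485) did not pass.

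Metal genes went both ways, with 14 of 27 rising, 7 falling and 21 passing when adjusted over the list alone. Nitrosocyanin (NE0143), a red copper protein of ammonia oxidisers, rose by 1.05 and mnxG (NE0315), a multicopper oxidase, fell by 1.53. merA, at -0.47, did not pass (adjusted p = 0.169). In the efflux list 13 of 29 rose and 5 fell, with 18 passing when adjusted over the list alone. NE0669, an inner membrane pump, fell by 1.75 and its neighbour NE0668, an outer membrane channel, by 1.13. Ribosomal protein genes rose in 29 of 56 cases and fell in 13, with 42 passing when adjusted over the list alone, rplQ rising by 1.00 and rpsU (NE0226) falling by 0.99. Carbon fixation genes fell in 8 of 15 cases and rose in 1, with 10 passing when adjusted over the list alone. cbbE (NE2148), an epimerase of the Calvin cycle, fell by 0.66, and rbcL by 0.51. Chaperone and protease genes rose in 10 of 21 cases and fell in 5, groEL (NE0028), the main chaperonin, rising by 1.01. Oxidative stress genes rose in 7 of 23 cases and fell in 9, the peroxidase-like NE2038 falling by 1.75. Of these 2 lists 15 and 16 genes passed when adjusted over the list alone. DNA repair genes rose in 9 of 23 cases and fell in 3, with 12 passing when adjusted over the list alone, and mutS (NE1705), a mismatch repair protein, rose by 0.71. Fatty acid synthesis genes rose in 6 of 11 cases and fell in 4, with 10 passing when adjusted over the list alone, and acpP (NE1649), the acyl carrier protein, rose by 0.64.

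In this comparison 1347 of 2383 genes passed limma's test, 736 higher and 611 lower in recovered cells. The change reached 2-fold in 89 of them, 29 higher and 60 lower. With normexp background correction 472 were higher and 1109 lower. All these counts include tRNA and other stable RNA probes. Of 40 tRNAs, 30 fell past the test, and the median log2 change of all 40 was -1.35. Many of the 2-fold falls are therefore tRNAs. Without stable RNA probes 741 genes were higher and 586 lower. The authors' deposited table lists 27 genes as higher and 36 as lower, and all of them moved the same way here. Of the genes called after exposure, 844 were called the opposite way in this comparison, 417 that had risen and 427 that had fallen. Independent lists of these sizes would share 431. Simulated unchanged groups give hardly any calls (a mean of 0.02 shared), so their count says little about the shared exposed arrays. By direction alone, 70.4% of all genes moved opposite ways, against 66.7% in the simulations. The simulations gave each gene the same spread in every group. The median SD between arrays was in fact 0.046 in control, 0.086 in exposed and 0.12 in recovered cells. The 66.7% is therefore no firm reference for these arrays. The exposed arrays could not be divided with 2 on each side, so part of the overlap beyond 431 may come from sharing them. Of the 195 genes with a 2-fold change on exposure, 139 were called the opposite way.

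The third comparison asks what still differed from untreated cells after the recovery. The control cells had not spent time in fresh medium, so a difference may come from the exposure or from that step. czcC was the most raised gene, at 6.26-fold (log2 change 2.65, SE 0.069, adjusted p = 4.72e-08), and czcB was raised 2.70-fold. merP stood 2.01-fold above control and merC at least 1.87-fold above it. Rh50, the ammonium transporter, was still 2.59-fold lower (log2 change -1.37, SE 0.094, adjusted p = 4.55e-06). Larger falls from control were in stable RNAs: tRNAPro3 (-1.68), tRNAArg3 (-1.59), ffs (-1.52) and tRNATrp1 (-1.49). After czcC the largest rise was in tRNALeu3 (2.26). Of 40 tRNAs, 15 were lower and 5 higher than control past the test. aniA was at 0.04 from control and did not pass (adjusted p = 0.854), while its neighbours NE0925 (-1.16) and NE0926 (-1.05) were still lower.

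Of the 27 metal genes, 11 were higher and 7 lower than control, with 18 passing when adjusted over the list alone, and mnxG was lower by a log2 change of -1.28. Fatty acid synthesis genes were higher in 9 of 11 cases and lower in 0, with 10 passing when adjusted over the list alone (camera adjusted p = 0.00427; adjusted p = 0.149 with an estimated correlation). plsX was higher by 1.24, fabH by 1.19 and fabG1 (NE1648), a reductase of chain elongation, by 1.14. Aminoacyl-tRNA synthetases were higher in 15 of 21 cases and lower in 2, with 17 passing when adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.149 with an estimated correlation). trpS (NE1727) was higher by 0.98 and glnS (NE2356) by 0.94. Carbon fixation genes were higher in 9 of 15 cases, cbbA (NE0324), the aldolase, by 0.78, and lower in 1, with 12 passing when adjusted over the list alone. Respiratory chain genes were higher in 14 of 29 cases, nuoE (NE1773) by 0.59, and lower in 6, with 20 passing when adjusted over the list alone.

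Flagella and chemotaxis genes were lower in 17 of 41 cases and higher in 1, with 18 passing when adjusted over the list alone (camera adjusted p = 0.00619; adjusted p = 0.836 with an estimated correlation). flgA (NE0301), needed to assemble the flagellar ring, was lower by a log2 change of -0.98. With only probes well above background on all 9 arrays this list gave adjusted p = 0.0691. ECF sigma factors, which direct transcription of small sets of genes, were lower in 10 of 20 cases and higher in 2, with 12 passing when adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.836 with an estimated correlation). NE1099 was lower by a log2 change of -0.92. The list also caught secF (NE1144), a subunit of the protein export machinery and not a sigma factor, which was higher by 0.74. Median centring gave this list an adjusted p of 0.0544. Iron uptake genes were lower in 14 of 41 cases and higher in 5, with 17 passing when adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.836 with an estimated correlation). The receptor NE0636 was higher by 1.40. The iron list gave camera adjusted p = 0.148 with only probes well above background on all 9 arrays, and 0.0544 with median centring.

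Ammonia oxidation genes were higher in 4 of 11 cases and lower in 0, with 4 passing when adjusted over the list alone. cyt_c552 was higher by 0.75 and amoC3 by 0.49, and nitrosocyanin, outside this list, by 0.96. amoA1 (-0.20, adjusted p = 0.225), amoB1 (0.36, adjusted p = 0.183) and hao2 (-0.04, adjusted p = 0.875) did not pass. rplI (NE0195), a ribosomal protein, was 3.03-fold higher, gatB (NE2073) 3.47-fold and NE1807, an RNA helicase, 3.59-fold.

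In all, 1394 of 2383 genes differed from control, 839 higher and 555 lower, and 102 reached 2-fold, 80 higher and 22 lower. Of called genes 60.2% were higher, against 34.8% with median centring. The authors' deposited table lists 54 genes as higher and 25 as lower, and all of them moved the same way here. Of the genes called after exposure, 869 still differed from control in the same direction, 546 higher and 323 lower. Independent lists would share 459, and the simulated unchanged groups shared 0, again for want of calls. By direction alone, 71.7% of all genes moved the same way in both, against 66.6% in the simulations. The simulated groups again had equal spreads, unlike these groups, so the 66.6% is no firm reference either. The control arrays could not be divided with 2 on each side, so part of the overlap beyond 459 may also come from sharing them. Of the 195 genes with a 2-fold change on exposure, 150 were still called the same way, 125 of 159 that had risen and 25 of 36 that had fallen.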

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

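The blocks for slide row, the filter on all 6 spots and the removal of stable RNA probes were chosen after seeing the data. The counts of called genes stayed within 1.5 times of the reported ones under every alternative of scaling, background, filter, block, variance model and arrays. For slide row as a block this is read only for recovered against exposed. A 2-fold threshold beside the adjusted p left 195, 89 and 102 genes in the 3 comparisons, stable RNA probes included. Of these, 61 were called the same way in both comparisons with control and 42 were called opposite ways. A plain test per gene with a 2-fold change and an unadjusted p gave 194, 88 and 102, with 61 and 42, and after adjustment it called 888 for recovered against exposed. Without 1 array the counts ran from 1378 (without control 1) to 1696 (without recovered 3) for exposed against control, 1164 (without exposed 2) to 1387 for recovered against exposed and 1172 (without control 1) to 1432 for recovered against control, and the overlaps from 723 to 948 and from 720 to 932. Of 60 list tests 11 passed, 9 to 12 without 1 array, 19 with normexp and 7 with median centring. With an estimated correlation 0 passed, and 41 passed with fry, which asks another question. The cause of these moves was not tested.

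The balance of directions moved with scaling and with background correction. For exposed against control 845 genes were higher and 695 lower, against 1120 and 458 with normexp, 731 and 917 with quantile normalization, 617 and 1036 with median centring and 721 and 895 in the authors' values. For recovered against control 839 and 555 became 715 and 753, 515 and 966 and 697 and 741 under the last 3 of these, and for recovered against exposed normexp turned 736 and 611 into 472 and 1109, while the share higher was 54.6% here, 55.1% with quantile normalization and 51.4% with median centring. The median of all genes moved too, and its shift for the 3 contrasts (exposed against control, recovered against exposed, recovered against control) was -0.17, -0.02 and -0.19 with median centring, 0.16, -0.18 and -0.09 with normexp and -0.10, 0.01 and -0.10 with quantile normalization. Of genes called both here and under the alternative, 7 (exposed against control) and 53 (recovered against exposed) had opposite signs with normexp and 1 (exposed against control) with quantile normalization. Among lists and named genes, the sign of the estimate changed as follows. With normexp it did for the flagella list for exposed against control (adjusted p = 0.528), and for NE0758 (0.24), NE1205 (0.25), NE1071 (0.0256), flhB (NE2487, 0.26) and NE1864 (0.25), and for recovered against exposed for NE0758 (-0.55), katA (NE1886, -0.14) and cheR (NE1861, -0.10). NE0758, NE1205 and flhB were not well above background on any exposed array, so their signs in these comparisons rest on background signal and no direction is read from them. For exposed against control amoC1 (NE0945), amoC2 (NE2064) and rbcL (NE1921) turned to -0.31, -0.45 and -0.23 with quantile normalization and to -0.31, -0.46 and -0.20 in the authors' values. The cause was not tested.

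The replicate block called 1496, 1256 and 1332 genes. Replicate numbers did not pair the arrays. Once each gene's group mean had been subtracted, the remaining values of same-numbered arrays correlated from -0.26 to 0.11. Among arrays of the other groups, 0 of 9 correlated best with their own number. Slide as a block, which removes recovered 3, called 1696, 1387 and 1421. On the slide of the other arrays, all controls and exposed 1 lay in row 1. Row 2 held exposed 2, exposed 3, recovered 1 and recovered 2. Group and position can therefore hardly be told apart. Slide row as a block called 1473 genes for recovered against exposed. Under that block both comparisons with control rest on exposed 1 alone, so no count is read from them. A median of several probes gave no value, since each gene had 1 probe. The control arrays did not show merC well above background, which limits its fold.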

Other observations

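The tests on tRNAs and most of those on gene runs below were chosen after the result was seen; the test of probe position in single genes and the other splits of the arrays were written before. The comparison of tRNAs with long stable RNAs was also revised after its first results, which had left out the spread of the reference RNAs and then the spread between arrays, and had argued against scaling. The patterns are hypotheses from the same data.

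Stable RNAs stood out beside the messenger RNAs. All 40 tRNA probes were higher in exposed than in control cells, 36 of them past limma's test, with a median log2 change of 1.11 and a range from 0.31 to 2.49. The 16S ribosomal RNA rose by 1.12, while the changes of the 23S ribosomal RNA (0.68, adjusted p = 0.158) and of the transfer-messenger RNA, which frees stalled ribosomes (0.54, adjusted p = 0.197), did not pass. In recovered against exposed cells 38 of 40 tRNAs were lower, 30 past the test, with a median of -1.35, and ffs, the RNA of the signal recognition particle (105 nt), was lower by a log2 change of -1.92. Against control, the 9 leucine and serine tRNAs (85 to 93 nt) had a median of 0.86 and the 31 shorter ones (74 to 77 nt) a median of -0.41.

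Silica columns and labelling may keep short RNA unevenly. For the fall in recovery, the shorter tRNAs dropped further than the longer ones, by a difference of medians of -0.99 (95% interval over RNAs -2.14 to -0.61, SE over arrays 0.33, two-sided permutation p = 0.0039, adjusted over 3 comparisons 0.00585). This difference was -0.57 without recovered 3, the array alone on its slide. Uneven recovery of short RNA would give it, but the longer tRNAs are exactly those for leucine and serine. Length therefore cannot be told from a change of these tRNAs, here or in the size comparison for exposure below. Of the 3 RNAs between the tRNAs and 300 nt, the 5S ribosomal RNA (118 nt, -0.61) and rnpB (285 nt, -0.44) changed less than the shorter tRNAs (median -1.44), but ffs at -1.92 goes against a loss by size alone. A larger share of messenger RNA on the recovered arrays would move long stable RNAs alike, and stays open: the tRNAs differed from those over 300 nt by -1.07, away from 0 over RNAs (95% interval -1.19 to -0.55) but within 2 standard errors of 0 over arrays (SE 0.54, arrays from -1.83 to -0.32), and by -0.63 without recovered 3, where the long RNAs had a median of -0.79 and not -0.28. For the rise on exposure, the same size comparison gave -0.34, which leans against more short RNA over arrays (SE 0.12, arrays from -0.50 to -0.20) but not over RNAs (95% interval -0.55 to 0.20), and it was -0.20 without exposed 1. The comparison with long stable RNAs gave 0.43, not away from 0 over RNAs (95% interval -0.14 to 0.69) or arrays (SE 0.36), and 0.73 without exposed 1 and 0.24 without exposed 3; a verdict needed both spreads, so neither explanation was excluded. A change of tRNA pools with the treatment was not tested separately and stays open.

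Along runs of genes on one strand, changes on exposure leaned down with distance from the first gene, as noticed in the ATP synthase, ribosomal protein, NADH dehydrogenase and czc genes. In 190 runs of 736 genes (gaps up to 50 bp) the slope was -0.044 log2 per kb (permutation p = 0.00011, adjusted 0.00022), and it was -0.035 and -0.034 with gaps of 30 and 100 bp, but only 107 runs fell and 83 rose, so the effect is small. Recovered against exposed gave 0.067 (57 runs falling, 133 rising), and recovered against control 0.023 (66 falling, 124 rising, permutation p = 0.00393, adjusted 0.00472), so recovered cells leaned the other way from control. A linear effect of probe brightness did not account for it, since the slope was -0.044 with the control level in the model (-0.04371, SE 0.012). The control level came from the same arrays as the change. Non-linear effects of brightness, and the slope under other scaling or background correction, were not tested. More intact RNA in exposed cells, labelled from the 3' end, stays open: in 612 single genes the change per kb of distance from the 3' end was 0.149 (SE 0.096), larger than the slope along runs but within 2 standard errors of 0. In the runs that had not prompted the test the slope was -0.038 (permutation p = 0.00124, adjusted 0.00186). Of them 98 fell and 80 rose, against 73 and 69 with gaps of 30 bp and 124 and 122 with gaps of 100 bp. The permutation shuffles genes within runs of the same arrays, so its p does not measure the spread between samples. That exposure lowers transcription of genes far from the start of a run is a hypothesis. These runs cannot tell it from more intact RNA in exposed cells.

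Each pair of groups allows 10 splits of its 6 arrays, too few for a share under 0.05. In fits to the 6 arrays alone the real split gave 1666 genes for exposed against control, 1166 for recovered against exposed and 1382 for recovered against control. In each case 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 0. Every other split put arrays of both groups on each side, so the group difference added to its spread and low counts were built in. The 0 therefore adds nothing to the calls themselves.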
